A study of Homo sapiens with 2 samples.

How the data were processed

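The study treated chromatin extracted from MCF-7, a human breast cancer cell line that carries the estrogen receptor, with the catechol estrogen 4OHEE2 or with the solvent acetonitrile (the mock). Per the labels' protocols, cells were crosslinked with 1% formaldehyde and the chromatin was released with 4000 gel units of micrococcal nuclease (MNase), an enzyme that cuts the DNA between nucleosomes. The incubated DNA was purified, a biotin-carrying click probe was introduced, and the labelled DNA was collected on streptavidin beads. A total of 10 ng of DNA pooled from 3 biological replicates was sequenced. There was thus 1 pooled library per group, 2 samples in all, and the spread between replicates cannot be measured.

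The data analysed here are 1 list of peaks, called on the treated pulldown with the mock pulldown as the control, per the peak names in the file. Per the submitters' processing notes, fastp 0.20.0, Bowtie2 2.3.4.3 and MACS2 2.2.4 were used, with GRCh38 (hg38) as the genome; parameters, duplicate removal and filters are not given in the sources used here. For each peak the deposited list holds a fold enrichment at the summit, which is a ratio of the treated pileup to the background from the mock. It also holds the deposited −log10 p and −log10 q of the caller's Poisson test, and a deposited score equal to 10 times the −log10 q cut to a whole number. These values are the authors', and the highest q in the list stands at the 0.05 threshold. No read counts per library were used, so the total depth of either library is unknown. A list called with the mock over the treated library was not analysed here, so the number of peaks that arise without treatment is open.

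The depth at each summit was rebuilt from the deposited fold and p-value. With the caller's pseudocount of 1, the fold is the treated pileup plus 1 over the mock background plus 1, and the p-value is the Poisson tail for that pileup and background. For all 13952 peaks a whole-number pileup gave both deposited values, with the −log10 p matched within 0.001. The next best pileup missed the −log10 p by at least 0.0073. In a test on 5477 simulated peaks the pileup was recovered in 100% of cases. The mock background is the caller's local estimate after its own scaling of the libraries, not a raw count. It has a floor at 2.22 fragments, at which 965 peaks stood.

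Gene positions came from the RefSeq gene table of GRCh38.p14, which gives the start and end of each gene without strand, exons or sequence. The planned promoter class was therefore replaced by the sequence within 1 kb of either end of a protein-coding gene, which holds promoters and transcript ends alike. Exons, introns and UTRs were not told apart, and the planned results on base composition and sequence motifs were not run. Summits were counted on chromosomes 1 to 22 and X, over the span between the first and last annotated gene of each chromosome. Stretches of more than 1 Mb without any annotated gene, mostly centromeres, were left out. This span measured 2852 Mb and held 13923 summits; 12 summits outside it were not used for the placement results.

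Each summit was assigned to the first class that held it, in the order gene end, protein-coding gene body, other annotated gene and intergenic. Shares were compared with 1000 random placements of the summits on the same chromosome, and the smallest p these can give is 0.0020. Intervals of ratios came from 1000 bootstrap resamples of 1 Mb bins (95%). Chromosomes and regions were tested with two-sided exact binomial tests. Nearby peaks are not independent, so these p-values are too small, and all p-values describe this 1 list and not the spread between experiments. For 9 gene lists the share of genes with a summit in the gene body or within 5 kb was compared with 10000 random lists of protein-coding genes matched on gene length in 20 bins. The smallest p these can give is 0.0002. Random lists treat neighbouring genes as independent, although such genes can share a summit. All p-values were two-sided and adjusted by the Benjamini-Hochberg method within each family. All 281 list entries matched a gene symbol or older name among 19970 protein-coding genes; FAM190A is an older name of CCSER1 and both were counted once. Median folds of annotation classes were compared by permutation tests across peaks with 10000 resamples. Coordinates are given 1-based on GRCh38.

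The list test was tested on simulated lists of 200 genes drawn from 19970. It called 0 of 20 lists with the background density of summits, 19 of 20 with a density of 2 times the background and 20 of 20 with 4 times. The lists used here are much shorter, so smaller excesses can be missed. The simulated summits were placed at random along each chromosome and the genes were drawn at random. The real summits are clumped and the real lists can hold neighbouring genes, so the 0 of 20 does not cover false calls that arise from clumping or gene density. The placement test was tested on simulated summits of which 5% had been moved to gene ends. It found 7.86% there against 3.11% expected (empirical p of 0.020 from random placements). That p came from fewer placements than the 1000 used for the data, and it is the smallest that they can give. With 0% moved, the empirical p was 0.59.

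Genes were named by a rule. It took the genes at the 20 peaks of highest fold, 10 genes with the highest-fold summit at a gene end, and the 10 genes with the most summits. It added up to 4 members of each list by fold, and 10 genes fixed by name. The design, the gene lists, the rule and most alternatives were set before the data were examined. The alternatives were a q under 0.001, the peaks at or above the median fold, merging peaks within 1 kb, leaving out the densest 1% of 1 Mb bins, other overlap rules, windows, backgrounds and list matching. An alternative limited to peaks whose fold could be called at any depth, and a comparison of folds within quintiles of the mock background, were added after seeing the data, the former after the mock background had been compared between regions. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.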

Results

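The series asked at which DNA sequences adducts of a catechol estrogen lie when chromatin of MCF-7 breast cancer cells is exposed to it. Catechol estrogens are estrogen metabolites that can be oxidised to quinones, which bind covalently to DNA bases. The data comprised 2 pooled pulldown libraries, 1 from chromatin incubated with 4OHEE2 and 1 from chromatin incubated with solvent. The peaks of the treated library over the mock were the only measurement used. Because each library pooled 3 biological replicates, no difference reported here has a replicate check.

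The list held 13952 peaks that together covered 4.89 Mb. Of these, 13935 lay on chromosomes 1 to 22 and X, 8 on mitochondrial DNA and 9 on unplaced or unlocalised contigs. Peaks were narrow, with a median width of 306 bp (quartiles 254 and 401 bp), and their enrichment was modest. The median fold over the mock was 3.35 (95% bootstrap interval over peaks 3.32 to 3.37), and 598 peaks exceeded 5-fold. The median summit rested on 19 treated fragments against a mock background of 4.95 fragments. The treated pileup ranged from 9 to 599 fragments and the background from 2.22 to 221 fragments. The q was under 0.001 for 7439 peaks (53.3%) and between 0.01 and 0.05 for 18.3%.

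The highest folds stood at single summits scattered over the genome. A 10.0-fold peak lay on the unplaced contig KI270438v1, and genes on contigs were not looked up. On chromosome 19 the summit of a 9.17-fold peak (43699347 to 43699764) lay 16569 bp from the nearest protein-coding gene, IRGC. The summit of a 9.02-fold peak (12513370 to 12513841) on the same chromosome lay 11752 bp from ZNF564. A 9.06-fold peak covered the annotated start coordinate of KIF23, a kinesin of cell division, at chromosome 15, 69414331 to 69414839, with 36 treated fragments over a background of 3.09. Beside KLF6, a zinc finger transcription factor on chromosome 10, a peak at 3785569 to 3785925 reached 8.59-fold, with its summit 481 bp outside the gene. ST14, a membrane serine protease gene on chromosome 11, held an 8.09-fold peak, and the gene of the T-box factor TBX3 on chromosome 12 held a 7.81-fold peak at 114674159 to 114674698 with 49 treated fragments. Of the other peaks among the 20 highest, those in PRORP (7.82-fold), CLCN4 (7.83-fold), OR14I1 (8.08-fold), and the overlapping LHCGR and STON1-GTF2A1L (7.52-fold) lay in gene bodies. Those nearest to ROBO2 (8.42-fold), FSTL5 (8.40-fold), FSCB (8.15-fold), BASP1 (8.11-fold), ATIC (7.54-fold) and LOC102723475 (7.78-fold) lay more than 10 kb from the gene. The distance was 691653 bp for FSCB, 582951 bp for LOC102723475 and 379938 bp for ROBO2, so these names only mark the nearest gene. The remaining peaks lay within 5 kb of COQ10B (8.40-fold), SCGN (8.12-fold) and PLA2G2A (7.54-fold).

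The fold that could be called depended on the depth of the mock. Where the background was at its floor of 2.22 fragments, the smallest called fold was 3.11, from a pileup of 9 fragments. Where the background was above 50 fragments, folds down to 1.36 were called, and the median fold of these 525 peaks was 1.85. In total 8669 peaks (62.1%) had a fold of 3.11 or more, and these are termed callable at any depth. The term is approximate, because pileups are whole numbers and a slightly higher fold was needed at some backgrounds just above the floor. The background shows no coverage below its floor, so a 3.11-fold site in DNA covered more thinly could also have gone uncalled.

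**Figure D1:**
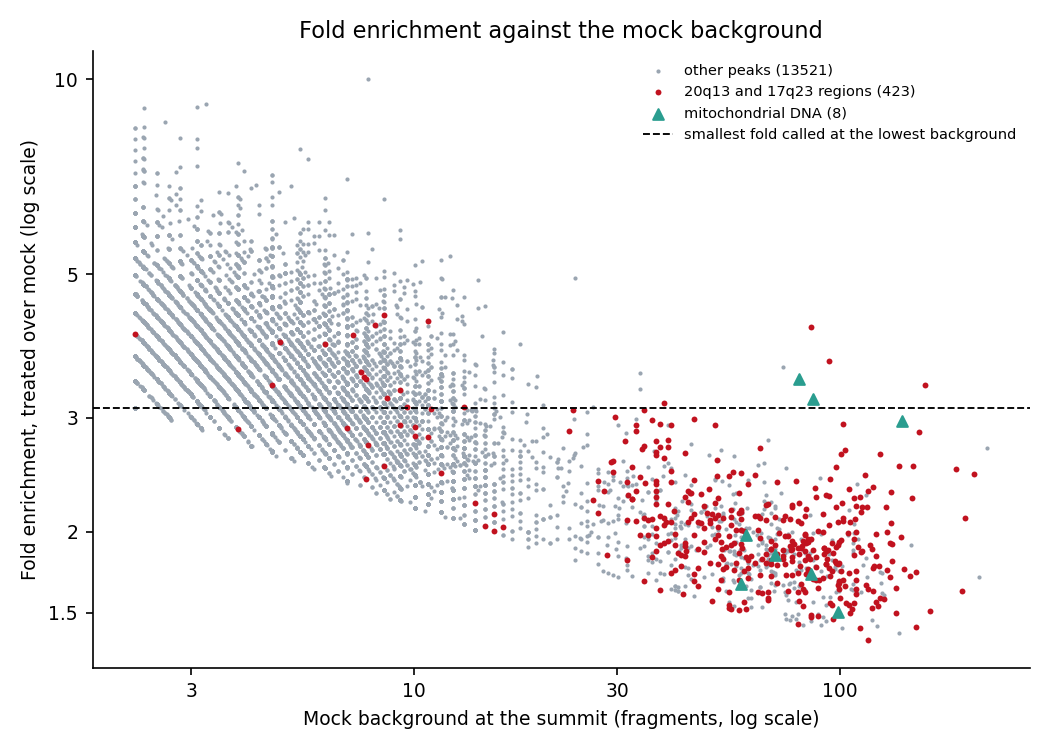
Fold enrichment of each peak (y axis, log scale, treated over mock) against the mock background at its summit in fragments (x axis, log scale). Grey points are peaks elsewhere, red points peaks of the 20q13 and 17q23 regions and triangles the 8 mitochondrial peaks; the dashed line marks 3.11-fold, the smallest fold called at the lowest background, and the lowest called fold declines to 1.36 as the background rises.

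Summits were spread unevenly over the chromosomes. Chromosome 20 carried 16.9 summits per Mb, chromosome 17 carried 14.5, the gene-rich chromosome 19 carried 13.9 and chromosome 16 carried 10.5, against 4.88 for the whole span. Their ratios to the number expected from length were 3.46 (95% bin bootstrap 2.19 to 5.06), 2.98 (2.13 to 3.99), 2.85 (2.37 to 3.41) and 2.14 (1.48 to 2.90). The gene-poor chromosome 18 had the lowest ratio, 0.36 (0.26 to 0.48), followed by X with 0.40 (0.31 to 0.50), chromosome 4 with 0.47 (0.38 to 0.58) and chromosome 13 with 0.51 (0.37 to 0.68). By exact binomial tests, 7 of 23 chromosomes lay above and 10 below expectation after adjustment. Chromosomes 5, 14 and 21 were among these although their bootstrap intervals include 1. At a q under 0.001, 5 lay above, as chromosomes 21 and 22 no longer passed. Without the densest 1% of bins 9 lay above, with chromosomes 12 and 15 added. In that setting 6 lay below, as chromosomes 1, 3, 5 and 10 no longer passed. Counts per 1 Mb bin were strongly clumped, with a variance 16.2 times the mean over 2796 full bins, and the 29 densest bins held 1947 of the summits. Among peaks that could be called at any depth the order changed, with ratios of 3.41 on chromosome 19, 2.04 on chromosome 17, 1.73 on chromosome 16, 1.72 on chromosome 22 and 1.55 on chromosome 20. The lowest ratios among these peaks were 0.49 on chromosome 18 and 0.51 on X. Without the 29 densest bins the ratio was 3.17 on chromosome 19 and 1.84 on chromosome 20. The median mock background at the summits was 13.1 fragments on chromosome 20 and 7.94 on chromosome 17. It was 3.99 on chromosome 19 and lowest on chromosomes 18 and X, at 3.09 on each.

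**Figure D2:**
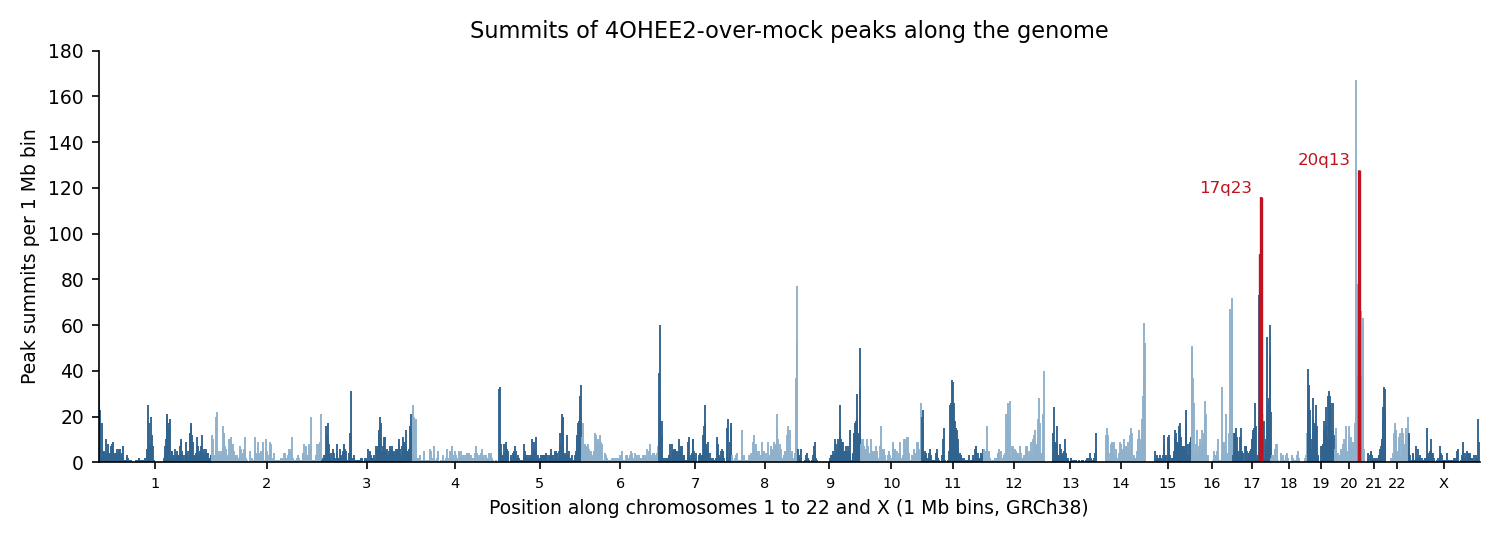
Number of peak summits in each 1 Mb bin (y axis) along chromosomes 1 to 22 and X (x axis, GRCh38, shades alternate between chromosomes), with bins of the 17q23 and 20q13 regions in red. The densest bin, on chromosome 20 from 47 to 48 Mb, held 167 summits, and the mean of full bins was 4.82.

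The regions of chromosomes 17 and 20 that are known to be amplified in MCF-7 stood out. The 20q13 region around ZNF217 and CYP24A1 (chromosome 20, 53067071 to 54673986) held 163 summits where 27.1 were expected from the chromosome mean, a ratio of 6.01 (exact 95% interval 5.18 to 6.91, adjusted p = 5.08e-74 by exact binomial test). The 17q23 region from VMP1 to BRIP1 (chromosome 17, 59207654 to 62363528) held 260 summits where 45.9 were expected, a ratio of 5.67 (5.07 to 6.30, adjusted p = 2.74e-114 by exact binomial test). Both intervals cover counting error only. The median mock background at these summits was 91.0 fragments in 20q13 and 51.7 in 17q23, and their median folds were 1.88 and 2.07. Among peaks that could be called at any depth, the excess was not present. The ratio was 0.13 in 20q13 (1 summit), which passed as below the chromosome mean (adjusted p = 0.026 by exact binomial test), and 0.92 in 17q23 (18 summits), which did not pass. Over the whole list the median fold was 4.04 at a background under 2.5 fragments and 1.85 above 50. The limit thus removes most summits at deep background, so these ratios cannot tell a true deficit or lack of preference from its effect. The 9p21 region around CDKN2A, which MCF-7 is known to have lost, held 2 summits where 6.02 were expected (ratio 0.33, 0.040 to 1.19, adjusted p = 0.14 by exact binomial test), and 0 lay between MTAP and CDKN2B themselves.

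Of the 10 protein-coding genes with the most summits, all but 1 lay on chromosomes 17 and 20. BCAS3 (chromosome 17) held 55 summits, or 7.59 per 100 kb, USP32 held 29, TEX14 held 26 and TRIM37 held 21. On chromosome 20, NCOA3, which encodes a coactivator of the estrogen receptor, held 40 summits (24.2 per 100 kb), ZMYND8 held 32, the growth factor gene BMP7 held 29 (26.9 per 100 kb), PREX1 held 26 and SULF2 held 23. GSE1 on chromosome 16 had 51 summits, or 9.87 per 100 kb, with a top fold of 4.49. Of these 10 genes, BMP7 had the deepest summit, with 599 treated fragments over a mock background of 221 and a fold of 2.70. Most of these summits had folds that could be called only at a deeper background. Among peaks callable at any depth, GSE1 held 15 summits, BCAS3 held 2, NCOA3, USP32 and TRIM37 held 1 each, and ZMYND8, BMP7, PREX1, TEX14 and SULF2 held 0.

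Summits were concentrated at the ends of genes. A share of 18.4% (2564 summits) lay within 1 kb of an end of a protein-coding gene, where random placement on the same chromosomes gave 3.12% (95% range 2.84 to 3.41), a ratio of 5.90 (95% bin bootstrap 5.56 to 6.27, n = 13923 summits, adjusted p = 0.0020). Gene bodies held 47.9% against 44.5% expected, a ratio of 1.08 (1.04 to 1.11). Other annotated genes, mostly long non-coding RNAs and pseudogenes, held 9.37% against 13.7% (ratio 0.68, 0.64 to 0.73), and intergenic sequence held 24.3% against 38.7% (ratio 0.63, 0.59 to 0.67). All 4 classes had an adjusted p of 0.0020, the smallest that 1000 placements can give. The ratio at gene ends was 2.86 against positions 10 kb to either side of the summits, and 2.98 with ends widened to 5 kb. Gene bodies turned to 0.93 and 0.86 under these settings.

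In total 2633 of 19970 protein-coding genes (13.2%) had a summit within 1 kb of an end. Besides KIF23, KLF6, SCGN, ST14 and LHCGR, the strongest were at the ends of CPAMD8 (7.34-fold), ASXL3 (7.32-fold), TALDO1, an enzyme of the pentose phosphate pathway (7.24-fold), SMO, the transducer of Hedgehog signalling (7.22-fold, 35 treated fragments) and FAM114A1 (7.22-fold). The table used here gives no strand, so starts and ends of transcription cannot be told apart at these sites.

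The size of the enrichment differed little between these places. The median fold was 3.38 at gene ends (n = 2564 summits), 3.32 in gene bodies (n = 6675), 3.40 in other genes (n = 1305) and 3.38 between genes (n = 3379). By permutation test across peaks, the median in gene bodies differed from that of intergenic summits by −0.059 (adjusted p = 0.026), while gene ends (adjusted p = 1) and other genes (adjusted p = 0.66) did not pass. The mock background was higher at gene ends than between genes, with medians of 5.40 and 4.63 fragments. When summits were compared within quintiles of the mock background, gene ends lay 0.14 above intergenic summits and gene bodies 0.029 above, and both passed the permutation test.

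**Figure D3:**
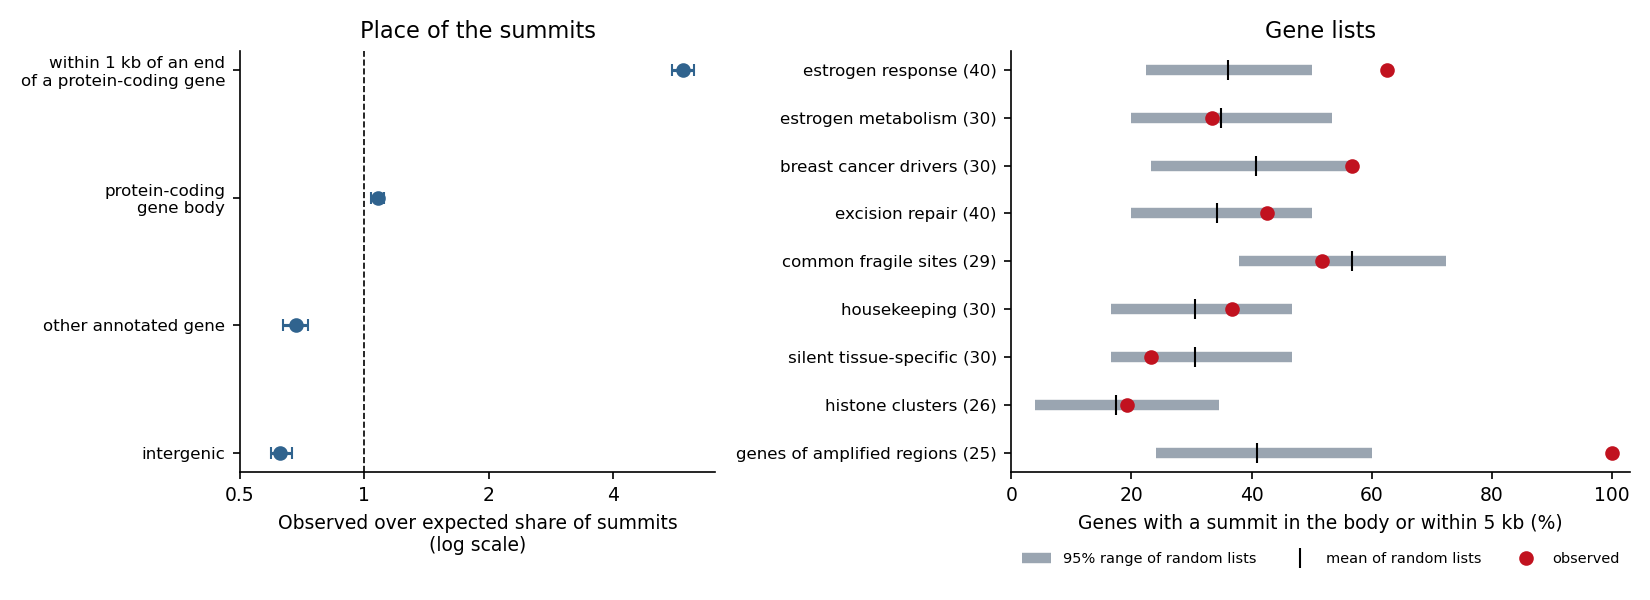
Left, observed over expected share of summits in each annotation class (log scale; bars are 95% bin bootstrap intervals), with gene ends at 5.90 and intergenic sequence at 0.63. Right, percentage of genes in each list with a summit in the gene body or within 5 kb (red points; number of genes in parentheses) beside the mean and 95% range of length-matched random lists; 2 lists lie beyond the range, estrogen response at 62.5% and genes of amplified regions at 100%.

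Genes of the estrogen response held summits more often than other genes of their length. Of 40 genes, 25 (62.5%) had a summit in the body or within 5 kb, where random lists gave 36.1% (95% range 22.5 to 50.0; ratio 1.73, n = 40 genes, adjusted p = 0.0027). GREB1, an early target gene of the estrogen receptor on chromosome 2, held 9 summits in 160 kb, the strongest 6.18-fold at 11592636 to 11593212 with 29 treated fragments. ESR1, the gene of the receptor itself on chromosome 6, held 4 summits with a top fold of 5.02, and FOXA1, a pioneer factor of the receptor on chromosome 14, had 4 summits with a top fold of 5.06. EGR3 had 1 summit at 5.75-fold, CCND1, the cyclin D1 gene, had 3 with a top fold of 4.60, MYC had 1 at 3.37-fold and TFF1 had 1 at 2.95-fold in its flank. At a q under 0.001 ESR1 held 1 summit and FOXA1 held 2, and among peaks callable at any depth ESR1 held 4, FOXA1 held 2 and TFF1 held 0. KRT8 and KRT18 lie side by side and shared the same summit. PGR, the progesterone receptor gene, had 0 summits. The call was lost among peaks callable at any depth (19 genes, ratio 1.72), among peaks at or above the median fold, with gene bodies alone and with 20 kb flanks, with ratios between 1.41 and 1.72.

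All 25 genes of the amplified regions held a summit, against 41.0% in random lists (ratio 2.44, n = 25 genes, adjusted p = 0.0018). The highest folds were in MED13 (4.32-fold), BCAS3 (4.24-fold), USP32 (4.14-fold) and TSHZ2 (4.04-fold). The summit in USP32 had 358 treated fragments, while that in TSHZ2 had 12 over a background of 2.22. At a q under 0.001 TSHZ2 held 0 summits. Among peaks callable at any depth 11 of these genes held a summit, and the list no longer passed (ratio 1.31).

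The other 7 lists did not pass. Of 30 breast cancer driver genes, 17 had a summit where 12.2 were expected (ratio 1.39, n = 30, adjusted p = 0.32). Among them TBX3 reached 7.81-fold, RUNX1 reached 5.32-fold, and BRCA1 had 4 summits with a top fold of 4.79, while TP53 had 0. Of 40 genes of base and nucleotide excision repair, 17 had a summit where 13.7 were expected (ratio 1.24, n = 40, adjusted p = 0.77). These included the glycosylase genes SMUG1 (4.32-fold), OGG1 (3 summits, top fold 4.09) and NEIL1 (3.88-fold), and DDB1 (4.08-fold). Of 30 genes of estrogen metabolism, 10 had a summit where 10.5 were expected (ratio 0.95, n = 30, adjusted p = 1). ARNT had a top fold of 4.03, AHRR had 5 summits with a top fold of 4.02, CYP19A1 (aromatase) had 2 summits with a top fold of 3.90 and COMT, which methylates catechol estrogens, had 2 with a top fold of 3.91. CYP1B1, which hydroxylates estrogens at the 4 position, had 0.

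Genes of common fragile sites, which are among the longest in the genome, had a summit in 15 of 29 cases where 16.4 were expected (ratio 0.91, n = 29, adjusted p = 0.91). Against lists matched also on the summit density of the bin the ratio was 1.49, which did not pass either. PTPRN2 held 14 summits with a top fold of 5.66, NAALADL2 held 8, AUTS2 held 3 with a top fold of 5.49, and CTNNA3 held 1 at 5.60-fold in 1851 kb. Housekeeping genes had a summit in 11 of 30 cases (expected 9.19, n = 30, adjusted p = 0.88), among them NPM1 (5.29-fold), YWHAZ (5.11-fold), TUBB (4.83-fold) and TPT1 (4.28-fold). Genes specific to other tissues did so in 7 of 30 cases (expected 9.16, n = 30, adjusted p = 0.88), among them NEUROD1 (5.60-fold), HBA1 (4.86-fold), SYT1 (3.63-fold) and GRIN1 (3.33-fold). HBA1 has a near-identical copy, so its reads are uncertain. Histone genes did so in 5 of 26 cases (expected 4.51, n = 26, adjusted p = 1). The members with the highest folds were H1-2 (3.73-fold), H1-4 and H2BC5, which shared a summit of 3.42-fold, and H2AC20, which shared a summit of 3.02-fold with H2BC21. At a q under 0.001 H1-2, H1-4 and H2BC5 held 0 summits.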

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

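The 8 peaks on mitochondrial DNA and the 9 on contigs lie outside the chromosomes on which places, genes and regions were compared, and enter only the description of the whole list. They are given because the caller placed them above the mock. The 8 mitochondrial peaks covered 11292 bp, with folds from 1.50 to 3.44 over a mock background of 58.6 to 140 fragments. Only 2 of the 8 reached the 3.11-fold that could be called at the lowest nuclear background. Their summits lay in RNR1 (1.66-fold), ND1 (3.21-fold), COX1 (1.50-fold), COX2 (1.98-fold), COX3 (3.44-fold) and ND5 (1.72-fold), and 2 lay outside the 37 annotated genes, with folds of 1.84 and 2.97. The peak that runs from 9063 to 13108 was the widest in the whole list at 4046 bp. On the contigs, the peak at 110175 to 111763 of KI270438v1 had the highest fold in the list, 10.0, with 87 treated fragments over a background of 7.79.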

How the results depend on the processing

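Of the alternatives to the main results of each comparison, 143 gave the same direction and side of the threshold, or a value or count close to the main result. Lists that passed under neither setting turned direction for fragile-site genes (1.03 callable at any depth, 1.49 matched on bin density), histone genes (0.69 at a q under 0.001, 0.95 callable at any depth, 0.92 with gene bodies alone, 0.85 matched on bin density), repair genes (0.92 with gene bodies alone), metabolism genes (1.06 with 20 kb flanks) and housekeeping genes (0.88 with 20 kb flanks); the fold of other genes against intergenic summits did so at or above the median fold (−0.0072) and without the densest bins (−0.020). With the call and direction the same, the size still depended on the setting: 20q13 had a ratio of 20.8 and 17q23 of 16.9 against the genome mean, and gene ends had ratios from 2.86 to 7.01. By construction, a q under 0.001 left 7439 peaks with a median fold of 3.78, and the peaks at or above the median fold numbered 7000 with a median of 3.92; merging peaks within 1 kb gave a median of 3.38. The variance to mean ratio per bin fell to 3.75 for peaks at or above the median fold, 4.95 for peaks callable at any depth and 7.39 without the densest 1% of bins; without those bins 6 chromosomes in place of 10 lay below expectation. The excess in the amplified regions turned into ratios of 0.18 (20q13) and 0.85 (17q23) for peaks at or above the median fold. For peaks callable at any depth these ratios were 0.13 and 0.92. Without the densest bins, 6 summits were left in 17q23, and its ratio of 1.87 did not pass. In 20q13, 35 summits were left without those bins, and the ratio of 6.66 passed as above the chromosome mean. By exact binomial tests, 20q13 passed as below the chromosome mean for peaks callable at any depth (adjusted p = 0.026) and did not pass at or above the median fold (adjusted p = 0.15), while its adjusted p was as low as 8.35e-150 where it lay above. That of 17q23 ranged from 1.21e-215 to 0.82, and the values below the mean did not pass. The list of amplified genes did not pass among peaks at or above the median fold (1.22) or callable at any depth (1.31). The estrogen response list did not pass at or above the median fold (1.69), callable at any depth (1.72), with gene bodies alone (1.65) or with 20 kb flanks (1.41). It passed with lists matched also on the summit density of the bin (1.50, n = 40 genes, adjusted p = 0.031), and its adjusted p ranged over all alternatives from 0.0027 to 0.13. Gene bodies fell below expectation against positions 10 kb away (0.93) and with gene ends widened to 5 kb (0.86). Within quintiles of the mock background the fold at gene ends rose to 0.14 above intergenic summits and that of gene bodies turned to 0.029 above; the cause of the other changes was not tested. At a q under 0.001, chromosomes 22 and 9 turned to 0.96 and 0.97. At or above the median fold, chromosomes 10, 7, 8 and 15 turned to 1.02, 1.01, 0.91 and 1.05, and among peaks callable at any depth chromosomes 7, 8 and 15 turned to 1.02, 0.94 and 1.08. Without the densest bins, chromosomes 5, 15, 8 and 11 turned to 1.01, 1.13, 0.95 and 1.07. The number of summits in single named genes moved under 80 alternatives. Among peaks callable at any depth it fell to 2 in BRCA1 and YWHAZ, 9 in PTPRN2 and 1 in ARNT, COMT and GRIN1; at a q under 0.001 it fell to 3 in NAALADL2 and AHRR. Base composition, sequence motifs, and every background matched on G+C or repeats were planned and not run, because no genome sequence was used here. No paired analysis was possible because each group is 1 pooled library, and no replicate could be left out. Depth limits the low-background parts of the genome, where folds under 3.11 were not detectable. The limit to peaks callable at any depth and the comparison within quintiles of the mock background were chosen after the data had been seen.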

Other observations

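The gene families with their values among peaks callable at any depth, the test of housekeeping gene ends without ribosomal protein genes and the test of depth near chromosome ends were chosen after the results were seen, the families in 2 rounds, with the second replacing the first. The tests of depth in amplified and gene-dense bins were chosen with the densities of all peaks known, and the test of all housekeeping gene ends with the preset housekeeping list and the share of ribosomal protein genes known. Families were taken by gene symbol and compared with length-matched random lists, with adjustment over 10 families. Genes of developmental transcription factors (PAX, SOX, TBX, FOX, GATA and related families) held summits in 108 of 165 cases (65.5%, expected 31.9%, n = 165 genes, adjusted p = 0.0005), and 29.1% had a summit within 1 kb of an end (expected 13.7%, adjusted p = 0.0010). HOX genes, which set position along the body axis, held summits in 27 of 39 cases (69.2%, expected 29.5%, n = 39, adjusted p = 0.0005), from 25 distinct summits. HOXD1 had a top fold of 5.22 and HOXA9 had 3 summits with a top fold of 4.45, both named after their values were seen. Clustered protocadherin genes, which encode adhesion molecules of neurons, held summits in 41 of 53 cases (77.4%, expected 41.0%, n = 53, adjusted p = 0.0005). These genes overlap, and the 41 rest on 23 distinct summits. Potassium channel genes held summits in 49 of 96 cases (51.0%, expected 38.8%, n = 96, adjusted p = 0.026). Neighbouring genes of a family share summits, so these p-values are too small. The median mock background at the summits was 6.94 fragments for the developmental factors, 6.17 for HOX genes and 6.79 for potassium channel genes, against 4.95 over the list. Among peaks callable at any depth the ratio to expectation passed for developmental factors (2.34), HOX genes (2.63) and protocadherin genes (2.18), and did not pass for potassium channel genes (1.19, n = 96, adjusted p = 0.35).

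Other families lay below expectation. Olfactory receptor genes held summits in 7 of 392 cases (1.79%, expected 25.2%, n = 392, adjusted p = 0.0005). Keratin and keratin-associated protein genes did so in 19 of 152 cases (12.5%, expected 21.5%, n = 152, adjusted p = 0.0083). Housekeeping families (ribosomal proteins of cytosol and mitochondria, proteasome, respiratory complex I with its assembly factors, initiation factors, spliceosome and RNA polymerase subunits) did so in 85 of 340 cases (expected 32.1%, n = 340, adjusted p = 0.0083). These families include the ribosomal protein genes, which had prompted the test of housekeeping gene ends. The share in the body or within 5 kb was not computed without them. The ZNF (30.6%, expected 34.6%, n = 517, adjusted p = 0.062), solute carrier (39.4%, expected 36.2%, n = 386, adjusted p = 0.23) and collagen genes (50.0%, expected 44.7%, n = 44, adjusted p = 0.56) did not pass. Matched also on the gene density of the bin, ZNF genes passed as below expectation (ratio 0.80, n = 517, adjusted p = 0.0003). Among peaks callable at any depth, with lists matched on length alone, the ratio was 1.00 for ZNF genes and did not pass, while olfactory receptor (0.072), keratin (0.53) and housekeeping genes (0.79) passed as below expectation.

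The share of genes with a summit within 1 kb of an end did not always follow. It was above expectation for collagen genes (31.8%, expected 12.9%, ratio 2.47, n = 44, adjusted p = 0.0040; ratio 2.06 and adjusted p = 0.11 among peaks callable at any depth), and for potassium channel genes (25 genes, expected 13.4%, n = 96, adjusted p = 0.0030). It was below expectation for olfactory receptor genes (0.26%, expected 12.5%, n = 392, adjusted p = 0.0010) and keratin genes (4.61%, expected 11.3%, n = 152, adjusted p = 0.011). HOX genes (28.2%, expected 14.8%, n = 39, adjusted p = 0.057) and protocadherin genes (3.77%, expected 13.6%, n = 53, adjusted p = 0.053) did not pass at gene ends, the latter with a share below expectation. At gene ends, the ratio among peaks callable at any depth was 2.29 against 2.12 over all peaks for developmental factors, 1.89 against 1.95 for potassium channel genes, 0.034 against 0.020 for olfactory receptor genes and 0.098 against 0.41 for keratin genes, and these passed in both. The ends of ZNF (11.8%, expected 13.2%) and solute carrier genes (15.3%, expected 13.2%) did not pass.

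The share of summits within 1 kb of gene ends was 5.90 times that of random placement, and bins with 20 or more protein-coding genes carried 15.0 summits per Mb against 0.884 in bins with none. Smaller folds made callable by deeper coverage of gene-dense bins do not account for the difference in density. The ratio of these densities was 13.9 (95% bin bootstrap 11.6 to 16.6) among peaks callable at any depth. Depth was known only at called summits, so bins covered too thinly for any call could not be seen. Lower coverage of bins without genes is thus not excluded. A preference for gene ends rich in G+C and CpG, whatever the gene's activity, would raise housekeeping genes too, most of which are known to have CpG-island promoters. Their gene ends held summits at a ratio of 0.53 to other genes of the same length (7.35% against 13.8%, n = 340, adjusted p = 0.0020), but this rests on the ribosomal protein genes, which had prompted the test (ratio 0.33, n = 154), and without them the ratio was 0.71 (9.68% against 13.6%, n = 186, p = 0.14). G+C, which was not measured, thus stays open as an explanation, and no biological explanation was tested.

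The 6 bins of 1 Mb that hold the 20q13 and 17q23 regions carried 16.4 times (95% bin bootstrap 9.84 to 23.1) the summit density of the rest of the genome. Among peaks callable at any depth the ratio to the rest of the genome was 1.49 (0.48 to 2.78), with 27 of the 464 summits left. The lower ratios given above for each region among these peaks were against the mean of its own chromosome. A fall from 16.4 to 1.49 would follow if deeper coverage of amplified DNA made smaller folds callable. The limit itself removes most summits at deep background, so it would also follow if these regions were preferred at smaller folds. The ratio and its interval thus cannot tell these apart or bound such a preference. No biological explanation was tested.

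Bins within 5 Mb of a chromosome end (short arms of chromosomes 13, 14, 15, 21 and 22 left out) carried 3.56 times (3.01 to 4.20) the summit density of other bins. Gene density, as matched here, does not account for all of it, since the ratio was still 2.43 (2.09 to 2.80) against other bins of the same class of protein-coding gene number. Smaller folds made callable by deeper coverage do not account for it either, with a ratio of 3.22 (2.82 to 3.67) among peaks callable at any depth. Depth was known only at called summits, so lower coverage of the other bins is not excluded. The G+C content of chromosome ends, which is known to be high, stays open as a technical explanation, and no biological explanation was tested.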
